A study of Danio rerio with 15 samples.

How the data were processed

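RNA from whole zebrafish larvae was measured in 15 libraries, 5 in each of 3 groups named Control, Low and High after the arsenic content of the diet fed to their parents. Per the labels' protocols, larvae were taken at 5 days post fertilization, RNA with an integrity number above 8 was used, and fragments were read from both ends over 100 bp on an Illumina NovaSeq instrument. The number 20 stands beside the larvae in the labels, without saying whether it is per sample. The authors deposited 1 table of whole-number read counts per Ensembl gene and library, with no normalization applied to the counts, per the file headers and the values themselves. The submitters' processing notes name FastQC, MultiQC, Trimmomatic and DESeq2 without versions, and the builds GRCz11 and mm10, the latter a mouse build. The aligner, the counting program, the gene annotation and the use of strand are not given in the sources used here. Reads from overlapping, antisense or near-identical genes therefore cannot be told apart in these counts, and values of such genes are uncertain.

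Each column was matched to its sample by the library name in the sample description, and every sample column was used. The table held 32520 genes and 15 trailing lines that name no gene and were left out. Symbols were taken from a table of gene names and matched 29201 identifiers. Of the genes, 6314 share a symbol with another identifier, many under capital-letter symbols given to both zebrafish copies of a gene, so identifiers are printed beside genes given with full statistics. Total counts per library ran from 21.2 to 59.9 M (mega counts), and 3585 genes had a total of 0. No pair of libraries was identical, and the chi-square per gene between libraries of a group was 18.1 or higher, so all 5 libraries of a group were kept as separate samples.

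Tests used R 4.3.3 and edgeR 4.0.16. Genes were filtered with filterByExpr at its defaults, which left 22012, and libraries were scaled with TMM factors. The quasi-likelihood test (robust) was fitted to all 15 libraries with 1 coefficient per group, and p-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. The comparisons were Low with Control, High with Control, High with Low, and a slope on diet arsenic over all libraries, with Control at 0. Standard errors of log2 fold changes are the fold change divided by the square root of the F statistic. CPM are counts divided by the TMM-scaled library total in M, and log2 CPM carry a prior count of 2. The common dispersion was 0.134, a biological coefficient of variation of 36.6%.

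Before the data were examined, the groups, the main test, most alternatives, 49 gene lists and the rule for naming genes were written down. The lists held 2055 written names. Of these, 1465 matched by symbol, 461 by symbol without its copy letter, 37 by synonym and 92 matched nothing. Lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the 49 lists of a comparison, and again with a correlation estimated per list and with fry. For each list, the count of members passing is given over all genes tested and adjusted over the list alone. The rule named, per comparison, the 10 genes that rose most and the 10 that fell most among those past the threshold with a mean log2 CPM of at least 1 and an informative symbol. It added up to 4 passing members with the smallest p of each list that camera called or that held 3 or more passing members, and 18 stress and endocrine readouts whether or not they passed. Where fewer than 5 genes passed, the 5 with informative symbols and the smallest p were named as not passing. It named 21, 44 and 62 genes in the 3 comparisons, and some members of long lists are summarised by count. A few genes under the rule are not reported here.

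The test was run first on simulated counts with the real means and library sizes. For High against Control with 21818 genes, 53.5% of 99 genes given a 2-fold change and 80.8% of 99 given a 4-fold change passed, with median fitted log2 fold changes of 0.98 and 2. Of 141 genes that passed, 8 (5.7%) had been given no change. In simulated Low and Control libraries with no change, 0 genes and 1 list passed. The simulated genes were drawn independently of each other, so this says little about lists of correlated genes in the real data. The estimated correlation within the liver list, for example, was 0.72. In other splits of the real Low and Control libraries, a median of 19 lists passed by camera at the preset correlation. A median of 0 and up to 1477 genes passed in these splits, so the simulated rates for single genes may not hold in the real data either.

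Alternatives were other scaling factors, no low-count filter, a filter of 1 CPM in 5 libraries, limma voom with sample weights, DESeq2 1.42.0, fits on the 2 groups compared, the replicate number as a block, stricter thresholds, the dose as a rank, and each library left out in turn. Alternatives added after seeing the data were a covariate for digestive-organ transcripts, 2 surrogate variables from sva 3.50.0, and a fit without Low 5, High 4 and High 5. The digestive covariate is the mean log2 CPM of the 136 tested genes of the lists for exocrine pancreas, intestine and liver. Other splits of the libraries into groups of the same sizes were drawn 100 times. The 3 libraries left out together were chosen for their globin and Hox transcripts.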

Results

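Gene expression was measured in whole zebrafish larvae whose parents had eaten arsenic through a natural food chain. Adults were fed for 60 days on blackworms (Lumbriculus variegatus), at 3.5% of body weight. The worms had first spent 14 days in water with sodium arsenite at 0, 2.5 or 5.0 mg/L. Worm arsenic was below 0.05 µg/g dry weight for Control and 72.47 µg/g for High. For Low the sample labels give 32.4 µg/g and the protocol text 33.42 µg/g. The offspring themselves were raised in arsenic-free medium and sampled at 5 days post fertilization, 5 libraries per group, per the sample labels. The design text of the series has the offspring reared to 30 days post fertilization, and does not tie that age to the sequenced larvae. Total counts, in M (mega counts), were 29.5, 23.8, 26.2, 25.2 and 59.9 in Control 1 to 5. They were 23.7, 27.2, 25.0, 25.7 and 22.6 in Low 1 to 5, and 36.1, 30.2, 24.9, 21.2 and 24.2 in High 1 to 5. The labels do not say that libraries came from separate clutches or sets of parents, so the p-values measure only the spread between these samples.

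Libraries of the same group differed widely in transcripts of the digestive organs. The list of exocrine pancreas and digestive enzymes had a mean log2 CPM of 6.30 in Control 2 and 5.17 in Control 4, against -1.08 to -0.71 in the other Control libraries. In Low it was 5.08 in Low 5 and -1.77 to 0.19 in the rest, and in High it was -0.98 in High 3, 0.91 in High 1 and 4.73 to 5.74 in the rest. The mean log2 CPM of 136 genes from the pancreas, intestine and liver lists was 2.29 ± 2.32 in Control, 0.94 ± 2.38 in Low and 3.59 ± 2.44 in High (SD, n = 5 each). These group means did not differ beyond the spread between libraries, with p = 0.39 for Low against Control, 0.43 for High against Control and 0.12 for High against Low (two-sided exact permutation tests; 0.43, 0.43 and 0.36 after Benjamini-Hochberg adjustment over the 3 tests). In a principal component analysis of all libraries the first component took 47.5% of the variance and the second 9.7%.

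**Figure D1:**
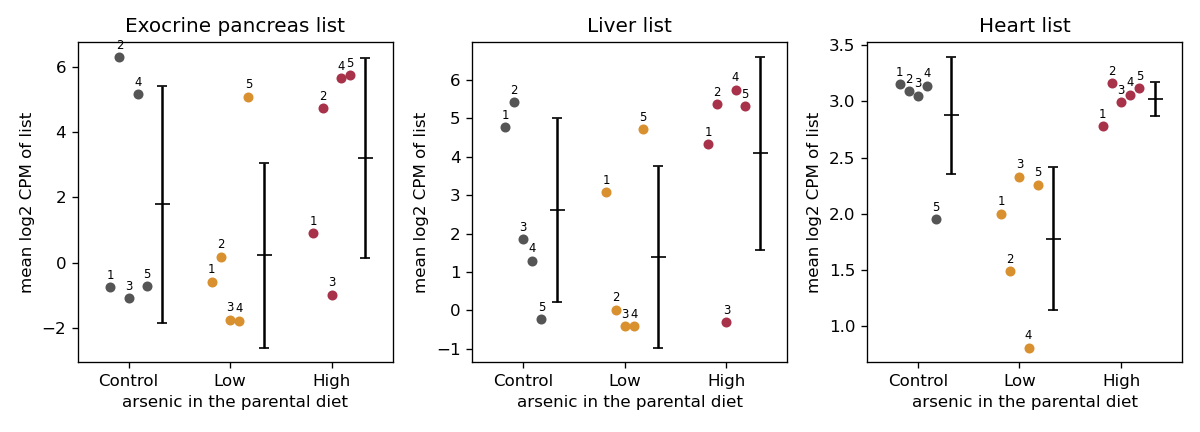
Mean log2 CPM over the genes of the exocrine pancreas, liver and heart lists (y axis) in each library, by the arsenic group of the parental diet (x axis). Numbered points are libraries and bars are means ± SD (n = 5). Pancreas values run from -1.77 to 6.30, and the heart value of Control 5, 1.95, lies below the other Control libraries.

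The comparison of Low with Control asks whether the smaller parental dose left a mark on the offspring. Transcripts of the heart list were lower in Low larvae, with a median log2 fold change of -1.08 over 29 genes, 24 of them below 0 (adjusted p = 3.6e-16 by camera, and 0.11 with an estimated correlation). By camera, lists of extracellular matrix, skeletal muscle and cartilage genes were lower too, and neuronal and neurotransmission lists slightly higher. With an estimated correlation none of these 5 passed, with adjusted p of 0.31, 0.4, 0.31, 0.6 and 0.42. No single gene passed. Expression of the heart list itself split by library: the mean log2 CPM was 3.05 to 3.15 in Control 1 to 4 and 1.95 in Control 5, against 0.81 to 2.33 in Low.

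For the heart list fry, which tests whether the members moved one way on balance, gave an adjusted p of 0.032. Of its 29 members 0 passed over all genes tested and 4 were lower adjusted over the list alone. The extracellular matrix list had a median log2 fold change of -0.36 over 60 genes, 54 of them below 0 (adjusted p = 2e-17 by camera and 0.31 with an estimated correlation), with 4 members lower adjusted over the list alone. For skeletal muscle the median was -0.41 in 75 genes (adjusted p = 1.7e-14 by camera and 0.4 with an estimated correlation), and 3 members were lower adjusted over the list alone. Low 5 stood apart from the other Low libraries in both, at a mean log2 CPM of 6.31 against 5.43 to 5.67 for matrix genes and 7.49 against 6.47 to 6.69 for muscle genes. Cartilage and bone genes had a median of -0.51 (adjusted p = 3e-10 by camera and 0.31 with an estimated correlation). Growth hormone, insulin and IGF genes had a median of -0.27 (adjusted p = 3.7e-05 by camera and 0.31 with an estimated correlation), with 3 lower adjusted over the list alone. Neuronal differentiation and synapse genes had a median of 0.16 (adjusted p = 5.9e-06 by camera and 0.6 with an estimated correlation), and those of monoamine, cholinergic, GABA and glutamate transmission 0.19 (adjusted p = 1.4e-05 by camera and 0.42 with an estimated correlation). The heat shock and cytosolic chaperone list was higher too, with a median of 0.2 and 33 of 43 genes above 0 (adjusted p = 0.00061 by camera, 0.31 with an estimated correlation and 0.15 by fry). Adjusted over that list alone, 0 members were higher and 1 lower. The digestive lists, which varied so much between libraries, had medians of -1.78 for pancreas, -0.77 for liver and -0.44 for intestine (adjusted p = 0.00048, 0.00018 and 0.00021 by camera, and 0.7 for each with an estimated correlation). Altogether 21 of 49 lists passed by camera, 3 higher and 18 lower, 0 with an estimated correlation and 2 by fry, the heart and thyroid lists. The thyroid list did not pass by camera (median -0.079, adjusted p = 0.14).

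Among single genes, edgeR's quasi-likelihood test called 0 of 22012, with 2098 (9.5%) at an unadjusted p below 0.05. DESeq2 called 62 and limma voom with sample weights 1436. Among the genes with the smallest p, 4 are given here, each with an adjusted p of 0.41 and below the Control mean in 5 of 5 Low libraries. The first was mylk2, a myosin light chain kinase (ENSDARG00000031698), at 1.63 ± 0.669 CPM in Control and 0.355 ± 0.145 in Low (SD, n = 5). The tropomyosin gene tpm4a (ENSDARG00000023963) had 49.2 ± 10.27 CPM in Control and 25.6 ± 6.18 in Low, a log2 fold change of -0.94 (SE 0.18). Values of mfap4.6 (ENSDARG00000094845) were 2.14 ± 0.955 and 0.456 ± 0.129 CPM, and the channel gene trpv1 (ENSDARG00000059883) had a log2 fold change of -0.66 (SE 0.13). These 4 passed the edgeR quasi-likelihood test when Low 5 was left out, with Benjamini-Hochberg adjusted p of 0.025 to 0.04. The count of genes without Low 5 was 507, of which 192 were higher and 315 lower, and without Low 5, High 4 and High 5, a fit added after the data were seen, it was 711. Low 5 was the Low library richest in digestive transcripts, so these fits cannot tell diet from digestive content.

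The comparison of High with Control addresses the larger dose. In larvae of High parents the cone genes ARR3 and CNGA3 and the chaperone genes dnajb1a and dnaja1 rose, and GNAT2, CEBPD and ATP1B2 fell. With 1 library left out, CEBPD and ATP1B2 were called in 10 of 10 fits, ARR3 and dnajb1a in 6, CNGA3 in 4, dnaja1 in 3 and GNAT2 in 1. Among the changes were a rise of slc24a2, a potassium-dependent sodium and calcium exchanger gene, from 29.7 ± 3.51 to 63.2 ± 7.85 CPM, and a fall of slc1a8b, of the glutamate transporter family, from 3.83 ± 1.73 to 0.372 ± 0.129 CPM (SD, n = 5). Heat shock and retinoic acid genes rose as groups (adjusted p = 1.2e-11 and 0.00085 by camera, and 0.023 for each with an estimated correlation). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 115 genes passed, 42 higher and 73 lower, and 37 of them changed at least 2-fold.

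The next 6 genes are among the 17 called in 10 of 10 edgeR quasi-likelihood fits that left out 1 library. The log2 fold change of slc24a2 (ENSDARG00000042988) was 1.09 (SE 0.14, Benjamini-Hochberg adjusted p = 0.005), and that of slc1a8b (ENSDARG00000032465) was -3.35 (SE 0.35, adjusted p = 0.0017). ATP1B2 (ENSDARG00000034424), a beta subunit of the sodium pump, fell from 7.46 ± 3.15 to 1.11 ± 0.165 CPM, a log2 fold change of -2.75 (SE 0.41, edgeR adjusted p = 0.011). CEBPD (ENSDARG00000087303), a transcription factor of the C/EBP family, fell from 147 ± 75 to 44.1 ± 6.42 CPM (-1.74, SE 0.26, edgeR adjusted p = 0.013); its Control 1 value was 277 CPM. The arrestin-domain gene ARRDC2 (ENSDARG00000020761) fell from 123 ± 21.1 to 46.4 ± 9.91 CPM (-1.40, SE 0.20, edgeR adjusted p = 0.0097). The nuclear receptor gene esrrd (ENSDARG00000015064) fell from 12.1 ± 0.797 to 4.92 ± 1.16 CPM (-1.30, SE 0.18, edgeR adjusted p = 0.0097).

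**Figure D2:**
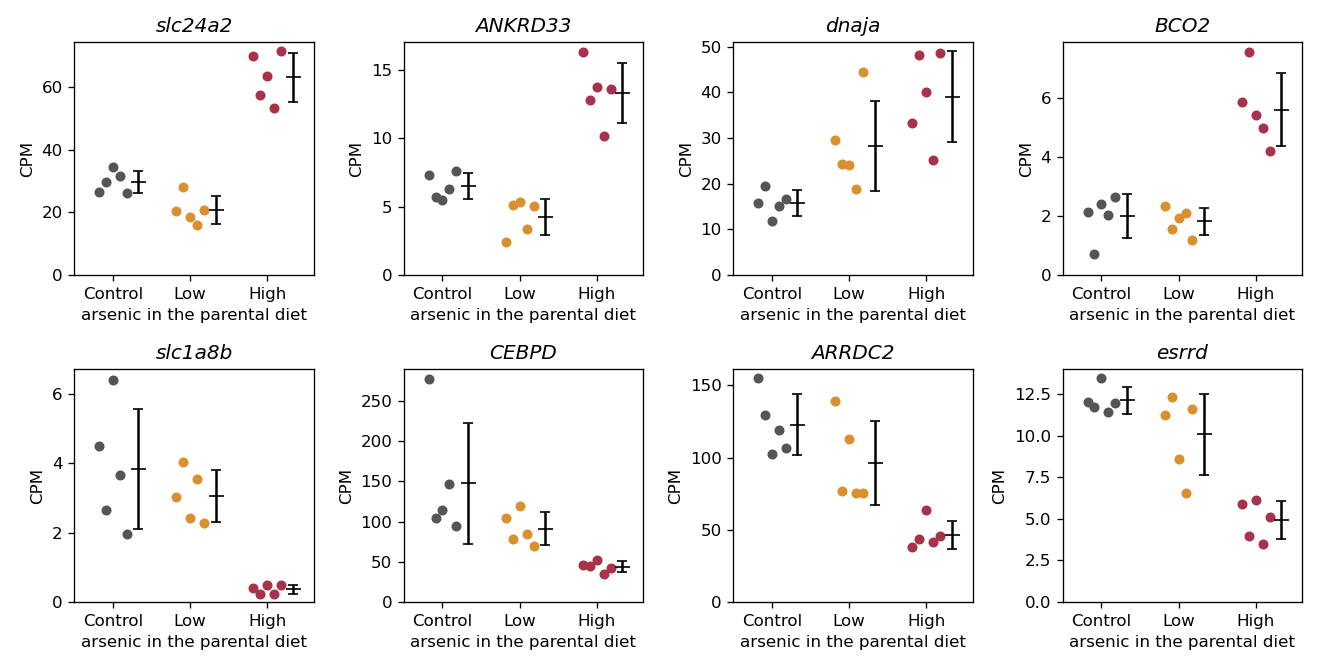
CPM of 8 genes (y axes, from 0) in each library, by the arsenic group of the parental diet (x axes). Points are libraries and bars are means ± SD (n = 5). In slc24a2, High libraries average 63.2 CPM and Control 29.7; in slc1a8b they average 0.372 and 3.83.

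Photoreceptor genes moved in both directions. Of 66 tested members of the phototransduction list, 3 rose and 1 fell (5 and 3 adjusted over the list alone), and the list as a whole did not pass (median -0.19, adjusted p = 0.25 by camera). ARR3 (ENSDARG00000098475), an arrestin of cones, rose from 37 ± 6.46 to 90.5 ± 25.1 CPM, a log2 fold change of 1.29 (SE 0.22, edgeR adjusted p = 0.022). CNGA3 (ENSDARG00000070726), a cone channel subunit, rose from 12.7 ± 1.87 to 22.6 ± 3.83 CPM (0.83, SE 0.16, edgeR adjusted p = 0.033), and GNAT2 (ENSDARG00000042529), the alpha subunit of cone transducin, fell from 362 ± 55.9 to 205 ± 30.1 CPM (-0.82, SE 0.17, edgeR adjusted p = 0.042). ANKRD33 (ENSDARG00000055638), outside the list, rose from 6.49 ± 0.958 to 13.3 ± 2.21 CPM (1.04, SE 0.20, edgeR adjusted p = 0.037). Leaving out 1 library kept the call of ARR3 in 6 of 10 fits, of CNGA3 in 4, of ANKRD33 in 3 and of GNAT2 in 1; their highest adjusted p were 0.072 and 0.091 without Control 4, 0.099 without High 1 and 0.11 without High 2.

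Heat shock and cytosolic chaperone genes rose as a group, with a median log2 fold change of 0.35 over 43 genes, 37 of them above 0. The call held with either treatment of the correlation (camera adjusted p = 1.2e-11, and 0.023 with an estimated correlation) and by fry (0.0022). Over all genes 3 members rose and 40 did not pass, and adjusted over the list alone 17 rose and 1 fell. The cochaperone dnajb1a (ENSDARG00000099383) rose from 10.9 ± 0.568 to 16.2 ± 1.09 CPM (0.57, SE 0.094, edgeR adjusted p = 0.02). AHSA1 (ENSDARG00000100317), an activator of Hsp90, rose from 29 ± 6.07 to 46.2 ± 4.1 CPM (0.67, SE 0.13, edgeR adjusted p = 0.036), and dnaja1 (ENSDARG00000030972) from 23.3 ± 3.11 to 34.2 ± 4.42 CPM (0.55, SE 0.11, edgeR adjusted p = 0.038). The related dnaja (ENSDARG00000051762) rose from 15.8 ± 2.8 to 39 ± 10 CPM (1.31, SE 0.23, edgeR adjusted p = 0.024). These 4 calls held in 6, 3, 3 and 5 of 10 fits without 1 library, with highest adjusted p of 0.072, 0.094 and 0.076 without Control 4 and 0.099 for dnaja1 without High 1. All 5 High libraries, at 4.40 to 4.67, had a higher mean log2 CPM of the list than every Control library, at 4.08 to 4.38. Low libraries, at 4.16 to 4.56, overlapped both groups.

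The retinoic acid and vitamin A list rose by a median of 0.24 over 31 genes, 24 above 0 (camera adjusted p = 0.00085, 0.023 with an estimated correlation, and 0.0031 by fry). Its passing members were the retinoid X receptor gene rxrga (ENSDARG00000005593), from 7.12 ± 0.451 to 10.18 ± 0.782 CPM (0.51, SE 0.089, edgeR adjusted p = 0.022), and BCO2 (ENSDARG00000041715), a carotenoid-cleaving enzyme, from 1.99 ± 0.744 to 5.6 ± 1.24 CPM (1.48, SE 0.29, edgeR adjusted p = 0.035). The calls held in 6 and 3 of 10 fits without 1 library, with highest adjusted p of 0.074 without Control 4 and 0.1 without High 2. Adjusted over the list alone 3 members rose. The retinol-binding gene rbp7a (ENSDARG00000091906), outside the list, fell from 17.2 ± 5.03 to 5.87 ± 1.4 CPM (-1.55, SE 0.25, edgeR adjusted p = 0.019; 0.063 without High 1), as did a gene named nmnat1-rbp7a (ENSDARG00000055893), whose name points to shared sequence, so both values are uncertain.

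**Figure D3:**
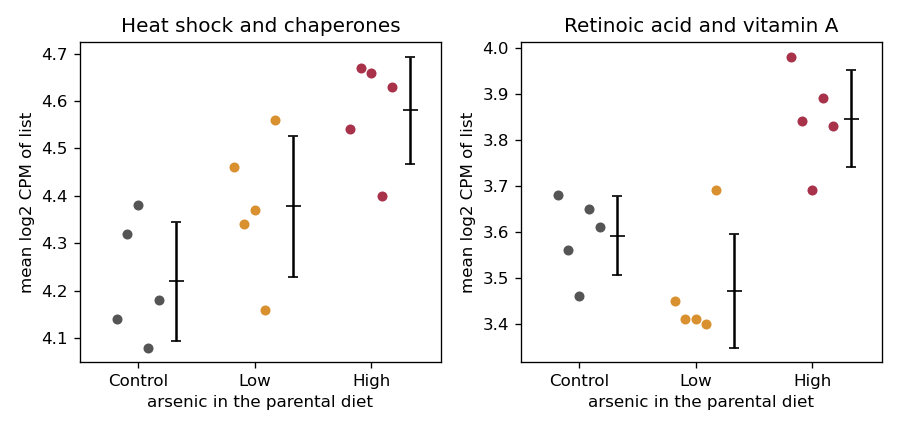
Mean log2 CPM over the genes of the heat shock and retinoic acid lists (y axes) in each library, by the arsenic group of the parental diet (x axes). Points are libraries and bars are means ± SD (n = 5). For heat shock, High libraries lie at 4.40 to 4.67 and Control libraries at 4.08 to 4.38.

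Several lists passed by camera alone. Cholesterol synthesis genes had a median of 0.78 (adjusted p = 1.1e-07, and 0.72 with an estimated correlation), with the lipoprotein receptor gene ldlrb (ENSDARG00000026759) as the 1 passing member, from 26.4 ± 4.54 to 44.1 ± 8.16 CPM (0.74, SE 0.15, edgeR adjusted p = 0.047; called in 2 of 10 fits without 1 library). Liver genes had a median of 1.16 with 0 passing members (adjusted p = 4.1e-05, and 0.86 with an estimated correlation); the liver mean was -0.3 in High 3 and 4.32 to 5.75 in the other High libraries. Pancreas and intestine lists did not pass (adjusted p = 0.15 and 0.09 by camera). Immediate early genes had a median of -0.23 (adjusted p = 4.1e-05, and 0.58 with an estimated correlation), with 8 members lower adjusted over the list alone. Their mean log2 CPM was 4.22 in High 3, the High library poorest in liver transcripts, which lay within the Control range of 4.03 to 4.38, and 3.64 to 3.90 in the other High libraries. The median of interferon and antiviral genes was -0.39 (adjusted p = 0.00012, and 0.72 with an estimated correlation), with High 3 again within the Control range of 2.25 to 2.61, at 2.47, and the other High libraries at 1.75 to 2.21. In the list of apoptosis and DNA damage genes (median -0.14, adjusted p = 0.007, and 0.55 with an estimated correlation) bbc3 (ENSDARG00000069282), a gene of apoptosis, fell from 10.4 ± 2.89 to 4.49 ± 1.44 CPM (-1.21, SE 0.24, edgeR adjusted p = 0.041; called in 3 of 10 fits without 1 library). In the growth hormone, insulin and IGF list (median -0.29, adjusted p = 6e-04, and 0.58 with an estimated correlation) the insulin receptor substrate gene IRS2 (ENSDARG00000075282) fell from 82.9 ± 8.16 to 50.7 ± 10.6 CPM (-0.71, SE 0.12, edgeR adjusted p = 0.022; called in 4 of 10 fits). In all, 22 lists passed by camera, 12 higher and 10 lower, and 2 with an estimated correlation.

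The remaining genes with large changes included NCOR1 (ENSDARG00000035285), a corepressor, at 28.8 ± 10.7 CPM in Control, 19.5 ± 18.9 in Low and 2.32 ± 0.658 in High (High against Control -3.63, SE 0.70, edgeR adjusted p = 0.042; called in 1 of 10 fits without 1 library). CDK8, pnp4a, YBEY (ENSDARG00000110510), ftr86 and skor1a rose by 0.83 to 1.42 on the log2 scale, and PRKCH (ENSDARG00000043243) fell by 1.07, with edgeR Benjamini-Hochberg adjusted p of 0.02 to 0.048, and were called in 2 to 6 of 10 fits. Of the 115 genes 17 had no informative symbol.

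The number of genes was 20 with the replicate number as a block, 941 by DESeq2, 254 by limma voom, 84 with the digestive covariate and 15 without Low 5, High 4 and High 5; the covariate ended the calls of CNGA3, GNAT2, AHSA1, dnaja1, NCOR1, bbc3, ldlrb and CDK8, at edgeR adjusted p of 0.051 to 0.057. It was 27, 29 and 19 without Control 1, 2 and 4, and 20, 35, 362, 38 and 49 without High 1, 2, 3, 4 and 5, and 17 genes were called in all 10 such fits.

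The comparison of High with Low sets the larger dose against the smaller one. The photoreceptor genes slc24a2, ARR3 and CNGA3 and the heart genes SLC8A1 and TNNI1 were higher in High, and the immediate early genes FOS and egr4 and the clock gene BHLHE40 were lower. The pigment epithelium isomerase gene RPE65 had 4.9 ± 0.905 CPM in Low and 47.3 ± 28.1 in High, and FOS 25.3 ± 9.47 in Low and 8.54 ± 1.18 in High (SD, n = 5). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 377 genes passed, 148 higher and 229 lower, 136 of them by at least 2-fold.

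In the phototransduction list 5 members rose and 2 fell (7 and 4 adjusted over the list alone), while the list did not pass as a whole (median -0.26, adjusted p = 0.59 by camera). The rise of slc24a2 from 20.8 ± 4.57 to 63.2 ± 7.85 CPM had the smallest p of the comparison (1.6, SE 0.14, edgeR adjusted p = 0.00021). ARR3 rose from 24.2 ± 7.27 to 90.5 ± 25.1 CPM (1.90, SE 0.22, edgeR adjusted p = 0.0024), and both CNGA3 copies rose, by 1.67 for ENSDARG00000012297 and 1.2 for ENSDARG00000070726 (edgeR adjusted p = 0.015 and 0.0059). ANKRD33 rose by 1.65 on the log2 scale (SE 0.21, edgeR adjusted p = 0.004). These 5 genes were called in 10 of 10 fits without 1 library. The retinoid cycle and pigment epithelium list had a median of 0.51 (camera adjusted p = 0.00024, and 0.37 with an estimated correlation), with 2 members passing over all genes and 6 adjusted over the list alone. Its RPE65 (ENSDARG00000007480) had a log2 fold change of 3.27 (SE 0.64, edgeR adjusted p = 0.027), but High 3 stood at 6.07 CPM and the call held in 2 of 10 fits, with a highest adjusted p of 0.083 without Low 3.

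The retinoic acid list rose with either correlation (median 0.28, camera adjusted p = 0.00013, 0.024 with an estimated correlation, and 0.00041 by fry), with Low 5 and High 3 both at a mean log2 CPM of 3.69, and with 3 members up over all genes and 7 up and 1 down adjusted over the list alone. They were rxrga (0.65, SE 0.089, edgeR adjusted p = 0.0072), BCO2 (1.62, SE 0.29, edgeR adjusted p = 0.018) and rbp5 (ENSDARG00000101481, 0.71, SE 0.17, edgeR adjusted p = 0.047), called in 10, 8 and 2 of 10 fits without 1 library. Heart genes had a median log2 fold change of 1.19 over 29 genes, 24 of them above 0 (camera adjusted p = 1.7e-11, 0.13 with an estimated correlation, and 0.0054 by fry), with 3 members passing over all genes and 13 adjusted over the list alone. The sodium and calcium exchanger gene SLC8A1 (ENSDARG00000013422) rose from 4.49 ± 1.06 to 11.9 ± 2.98 CPM (1.41, SE 0.25, edgeR adjusted p = 0.018). The troponin genes TNNI1 (ENSDARG00000052708) and TNNT2 (ENSDARG00000020610) rose from 6.47 ± 2.15 to 19.3 ± 5.21 and from 19.9 ± 6.94 to 45.4 ± 11.5 CPM (edgeR adjusted p = 0.023 and 0.043). The calls of these 3 genes held in 8, 7 and 1 of 10 fits, with highest adjusted p of 0.053 and 0.11 without Low 4 and 0.07 for TNNI1 without Low 1.

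Immediate early genes, switched on briefly after cell stimulation, had a median of -0.18 (camera adjusted p = 0.0064, and 0.56 with an estimated correlation), with 3 members lower over all genes and 11 lower and 1 higher adjusted over the list alone. FOS (ENSDARG00000031683) had a log2 fold change of -1.57 (SE 0.25, edgeR adjusted p = 0.015) and kept its call in 10 of 10 fits without 1 library, but Low 5, at 9.68 CPM, lay among the High libraries (6.79 to 9.80) and apart from the other Low libraries (23.6 to 34), and the adjusted p was 0.059 with the digestive covariate. The mean log2 CPM of the list was 3.79 in Low 5 (3.92 to 4.25 in the other Low libraries) and 4.22 in High 3 (3.64 to 3.90 in the other High libraries). The transcription factor gene egr4 (ENSDARG00000077799) fell from 40.6 ± 17.5 to 9.25 ± 2.06 CPM (-2.14, SE 0.41, edgeR adjusted p = 0.024), with 10.18 CPM in Low 5. NPAS4 (ENSDARG00000055752), induced by activity in neurons, fell from 57.9 ± 24.5 to 23.2 ± 6.33 CPM (-1.32, SE 0.30, edgeR adjusted p = 0.045). The calls of egr4 and NPAS4 held in 3 and 1 of 10 fits, with highest adjusted p of 0.076 without High 2 and 0.12 without Low 4. In the circadian clock list, which did not pass (median -0.078, adjusted p = 0.31 by camera), 4 members fell, BHLHE40 (ENSDARG00000004060) from 70.6 ± 15.5 to 31.9 ± 4.06 CPM (-1.14, SE 0.21, edgeR adjusted p = 0.018), PER1 (ENSDARG00000012499), PER3 and rorcb; these held in 6, 2, 2 and 2 of 10 fits.

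The Nrf2 and oxidative stress list had a median of 0.18 (camera adjusted p = 0.00059, 0.37 with an estimated correlation, and 0.02 by fry), and its 1 passing member, nfe2l2b (ENSDARG00000089697), rose from 2.08 ± 0.615 to 4.99 ± 0.505 CPM (1.26, SE 0.20, edgeR adjusted p = 0.015), in 10 of 10 fits without 1 library. The heat shock list had a median of 0.22 (camera adjusted p = 0.00064, 0.37 with an estimated correlation, and 0.036 by fry), with HSPB7 and CHORDC1 (ENSDARG00000017067) passing, in 6 and 2 of 10 fits. In the apoptosis and DNA damage list, which did not pass (adjusted p = 0.25 by camera), the cell cycle inhibitor gene cdkn1a rose by 1.28 and SESN1 and bbc3 fell by 0.88 and 1.13 on the log2 scale (edgeR adjusted p = 0.024, 0.028 and 0.034), in 3, 4 and 3 of 10 fits. The cell cycle list had a median of 0.39 with 0 passing members (camera adjusted p = 1.5e-08, and 0.56 with an estimated correlation); its mean log2 CPM was 4.99 in Low 5 and 3.64 to 3.84 in the other Low libraries. Liver, pancreas and intestine lists had medians of 2.11, 1.83 and 1.27 with 0 passing members (camera adjusted p = 2e-10, 8.1e-05 and 4.3e-05, and 0.56 for each with an estimated correlation), along with the spread of digestive transcripts described above. In all, 29 lists passed by camera, 24 higher and 5 lower, 1 with an estimated correlation and 5 by fry.

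Of the largest changes the text has not yet named, slc1a8b fell by 3.03 on the log2 scale in 10 of 10 fits without 1 library (edgeR adjusted p = 0.0019). The chemokine gene ccl19a.2 fell by 3.75, NCOR1 by 3.07, plekhs1.1 by 2.44, ATP1B2 by 2.21, ly6m6 by 2.15, plekhs1.3 by 1.90 and grk5 by 1.53, with edgeR Benjamini-Hochberg adjusted p of 0.018 to 0.045. Higher genes were tgm5l (2.45), spink2.9 (1.77), CSRP3 (1.75), pnp4a (1.73), muc5.2 (1.67) and SPR (ENSDARG00000058553, 1.67), with edgeR adjusted p of 0.015 to 0.047. Of these, the call of pnp4a held in 10 of 10 fits without 1 library, and those of the others in 2 to 7.

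The number of genes was 106 with the replicate block, 65 with the digestive covariate, 232 with surrogate variables, 1662 without Low 5, High 4 and High 5, 1663 by DESeq2 and 4575 by limma voom. It was 72, 231, 39, 63 and 3778 without Low 1 to 5, and 129, 56, 113 and 200 without High 1, 2, 4 and 5, and 32 genes were called in all 10 such fits. The 3778 genes came from the fit without the Low library richest in digestive transcripts, which cannot tell diet from digestive content. Of the 46 genes named by the rule and called here, the digestive covariate ended the calls of 32. Among them were FOS, egr4, BHLHE40, RPE65, SLC8A1 and TNNI1, at edgeR adjusted p of 0.051 to 0.09, and NPAS4 and NCOR1, at 0.17 and 0.18.

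A slope on diet arsenic over all 15 libraries passed in 63 genes, 23 with a rising and 40 with a falling slope (smallest edgeR adjusted p = 0.0073), and all 63 also passed in the same direction between High and Control, which uses the same libraries. A slope can pass where High alone differs, and Low against Control had 0 genes. The slope therefore does not show a graded response to dose. The count was 1 without Low 5, High 4 and High 5, 11 with the replicate block, 812 by DESeq2, 14, 10, 7 and 106 without Control 1, 2, 4 and 5, 34 and 41 without Low 1 and 2, and 4, 3, 141, 6 and 4 without High 1 to 5.

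The fold changes of Low and High against the shared Control libraries had a correlation across genes of 0.16. Genes are not independent replicates, and unchanged groups simulated against the same controls gave 0.51 (0.46 to 0.54 in 20 simulations). The covariance was 0.027 against a simulated 0.083, a difference of -0.056, and with the Control libraries split between the comparisons the mean correlation was -0.17 (-0.45 to -0.015 over 20 splits). Simulated genes were drawn independently of each other, without the spread of digestive transcripts between real libraries. The simulated ranges thus do not show what chance gives in these data, and whether Low and High effects agree or oppose each other stays open. The genes called in both numbered 0, as Low against Control had 0 by edgeR's quasi-likelihood test, and 8 by DESeq2.

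Of the readouts fixed in advance 15 were tested and are given here, and none of the 15 passed in any comparison by edgeR's quasi-likelihood test. The smallest Benjamini-Hochberg adjusted p was 0.57 for Low against Control, 0.24 for High against Control and 0.15 for High against Low. AS3MT, which methylates arsenic, had 14.7 ± 1.37, 13.7 ± 2.64 and 14.9 ± 1.75 CPM in Control, Low and High (SD, n = 5). The heat shock gene hsp70.1 had 11.7 ± 3.83, 15.8 ± 4.5 and 17.5 ± 3.73 CPM, and the heme oxygenase gene HMOX1 6.54 ± 1.75, 7.71 ± 2.45 and 7.66 ± 1.69 CPM. Values of catalase (CAT) were 165 ± 40.4, 141 ± 56.4 and 226 ± 69.7 CPM, and those of CYP1A1 26.2 ± 8.79, 20.6 ± 19.4 and 35.3 ± 12.8 CPM. Without Low 5, at 242 CPM of CAT and 55.2 of CYP1A1, both passed between High and Low (0.96 and 1.57 on the log2 scale, edgeR adjusted p = 0.014 and 0.0069). Low 5 was the Low library richest in digestive transcripts, at a digestive mean of 4.92 against -0.78 to 1.32 in the other Low libraries. High 3 was at -0.45 and the other High libraries at 3.04 to 5.4. In digestive-rich Control 2, CAT and CYP1A1 had 222 and 36.5 CPM, and in digestive-poor Control 5 they had 135 and 15.45. The fit without Low 5 therefore cannot tell diet from digestive content. DNMT1 had 68.9 ± 18.2, 67.4 ± 24.7 and 83 ± 36.5 CPM, and TH, the first enzyme of dopamine synthesis, 2.18 ± 0.678, 2.1 ± 0.41 and 2.15 ± 0.534 CPM. The remaining 8 readouts (gsto1, gstp1.2, GCLC, SOD1, MAT1A, ACHE, IGF1 and ESR1) did not pass either. The metallothionein gene mt2 matched no identifier, and the yolk gene vtg1 had 44 counts in total and was not tested.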

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

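Of the tests reported here, those on a missing body region, on parental diet as the source of digestive transcripts, on digestive content as the source of the gene calls, and on exchanged labels were chosen after the result was seen.

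Values were set apart where 1 library lay far from the other 4 of its group by Dixon's test. This held for 38 of 357 groups of values, where chance would give about 17.85, 1 in 20. Many are Low 5. Its mean log2 CPM was 6.31 for extracellular matrix (5.43 to 5.67 in the other Low libraries), 7.49 for skeletal muscle (6.47 to 6.69), 4.99 for cell cycle (3.64 to 3.84), 5.07 for intestine (-0.41 to 0.41) and 5.08 for exocrine pancreas (-1.77 to 0.19). It was 4.43 for aryl hydrocarbon receptor and phase I and II genes (2.29 to 2.49), 5 for cholesterol synthesis (3.18 to 3.57), 3.69 for retinoic acid genes (3.40 to 3.45), 4.83 for Nrf2 genes (4.33 to 4.42) and 2.83 for leukocytes (3.38 to 3.59). Among single genes Low 5 had 242 CPM of CAT (others 111 to 125), 55.2 of CYP1A1 (9.8 to 15.2), 110 of DNMT1 (48 to 65.6), 10.18 of egr4 (43.7 to 54.7), 264 of ctsla (179 to 196), 6.68 of cdkn1a (2.75 to 3.16) and 5.91 of PER1 (10.15 to 10.85).

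Control 5 had a total of 59.9 M counts (23.8 to 29.5 in the others) and a heart list mean of 1.95 (3.05 to 3.15). Control 2 had a cell cycle mean of 3.51 (4.36 to 4.68), 6.42 CPM of MAT1A (1.41 to 2.19), 25.8 of ARR3 (37.6 to 42.1), 3.01 of muc5.2 (11.4 to 14), 4.56 of plekhs1.1 (1.87 to 2.6), 33.4 of egr4 (10.7 to 16.6), 13.5 of plekhs1.3 (4.14 to 6.2) and 81.9 of BHLHE40 (39.2 to 44.7). Control 1 had a mean of 4.24 for the apoptosis and DNA damage list (3.96 to 4.03) and 277 CPM of CEBPD (94.4 to 147). In Low, CDK8 stood at 5.7 CPM in Low 2 (3.01 to 3.73) and rorcb at 158 CPM in Low 1 (110 to 123). High 3 had a liver mean of -0.3 (4.32 to 5.75), a hatching gland and yolk mean of 4.67 (6.72 to 7.38) and 63.5 CPM of ARRDC2 (38.4 to 45.4). High 4 had a blood vessel mean of 3.41 (3.77 to 3.91), an apoptosis and DNA damage list mean of 3.69 (3.85 to 3.91), 147 CPM of DNMT1 (56.3 to 76.4) and 0.0464 of ESR1 (0.491 to 0.63).

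The largest pattern is the spread of pancreas, liver and intestine transcripts between libraries of one group, from -0.38 to 5.58 in Control on the mean log2 CPM of their 136 genes. Depth and the counts taken by these genes are argued against as the source, since the range in Control was 0.98 of its size after thinning every library to the smallest total and 1 of its size with the digestive genes left out of totals and scaling. A body region missing from some libraries may be the source and stays open: with group means removed, the digestive mean correlated across the 15 libraries with the heart list at rho 0.45 (permutation p = 0.095, adjusted 0.13; r = 0.49, p = 0.062, adjusted 0.07; 0.5 without the 2 farthest libraries) and with skeletal muscle at rho 0.41 (p = 0.13, adjusted 0.13; r = 0.48, p = 0.07, adjusted 0.07; 0.51 without the 2 farthest). The spread was present without added arsenic, as Control had a range 1.03 of the mean range in Low and High. All libraries of a group share 1 diet level, so this comparison cannot show whether diet arsenic moves digestive transcripts between groups. Differences between parents, which were not tested, and developmental pace stay open; the hatching gland and yolk list, which shares members with the intestine and liver lists, was likewise at 7.43 in Control 2 and 4.60 in Control 5, at 7.54 in Low 5 (4.26 to 5.52 in the rest) and at 4.67 in High 3 (6.72 to 7.38 in the rest).

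Digestive content could in turn be the source of genes called between groups. With the digestive mean as a covariate, the median absolute log2 fold change of the called genes was 0.99 of its size in High against Control and 0.97 in High against Low, and all 115 and 377 genes kept their sign. The called genes are ones whose spread within groups was small, so a covariate that varied widely within groups could hardly move their folds. These folds therefore cannot decide whether digestive content is a source of the calls. Over all genes tested, those at an unadjusted p below 0.05 by edgeR's quasi-likelihood test went from 4814 to 3390 in High against Low with the covariate. In High against Control they went from 3480 to 3449. In High against Control 72 of 115 calls held, with a median SE of 0.14 before and after. In High against Low 59 of 377 held, with a median absolute fold of 0.8 before and 0.78 after and a median SE of 0.17 and 0.18; 318 calls ended, at a median adjusted p of 0.093, as the median p of the 377 genes went from 0.00028 to 9e-04 while the largest p that passed went from 0.00085 to 0.00015.

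Low 5 and High 3 each resemble the other group in digestive transcripts, and exchanged labels are a candidate explanation. On 734 genes called between High and Control in a fit without either library, with the Control mean at 0 and that of the other High libraries at 1, High 3 lay at 0.41 and Low 5 at 0.46, against -0.029 to 0.28 for the other Low and 0.9 to 1.29 for the other High libraries. On 500 genes outside the digestive lists that best set High apart from both Low and Control in such a fit, with the other Low libraries at 0 and the other High at 1, High 3 lay at 0.49 and Low 5 at 0.57. Other libraries left out as pairs in the same way lay at -0.18 to 0.33 in Low and 0.67 to 1.13 in High, so both libraries fell between the groups and the exchange cannot be told apart from other sources of their position. Genes called with both libraries in the fit, such as slc24a2 at 63.5 CPM in High 3 and 20.8 in Low 5, lie with their own groups but were selected with these labels, and no group or label was changed.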

How the results depend on the processing

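The digestive covariate, the surrogate variables and the fit without Low 5, High 4 and High 5 were chosen after seeing the data; the other alternatives were fixed before. Genes called in Low against Control numbered 0 except for 1 with the replicate block, 711 without Low 5, High 4 and High 5, 1436 by limma voom, 62 by DESeq2 and 0 to 507 when 1 library was left out, the 507 without Low 5. In High against Control (115 genes) the counts outside 1.5 times were 20 with the replicate block, 294 with surrogate variables, 15 without the 3 libraries, 254 by limma voom, 941 by DESeq2, 51 with only the 2 groups in the fit, 37 at a 2-fold minimum, 10 at an adjusted p of 0.01 and 19 to 362 with 1 library left out. In High against Low (377) they were 106 with the block, 65 with the digestive covariate, 232 with surrogate variables, 1662 without the 3 libraries, 4575 by limma voom, 1663 by DESeq2, 118 with only the 2 groups, 136 at a 2-fold minimum, 13 at an adjusted p of 0.01 and 39 to 3778 with 1 library left out. For the slope on diet arsenic (63) they were 39 with no low-count filter, 11 with the block, 119 with surrogate variables, 1 without the 3 libraries, 812 by DESeq2, 3 at an adjusted p of 0.01 and 3 to 141 with 1 library left out. Lists called went from 21, 22 and 29 to 0, 2 and 1 with an estimated correlation and to 2, 2 and 5 by fry; leaving out 1 library gave 15 to 24, 18 to 28 and 25 to 31. Genes called in both Low and High against Control were 0, and 8 by DESeq2. The correlation of their fold changes, 0.16, was 0.1 with the block, 0.36 by DESeq2, 0.19 to 0.3 without 1 Control library, and reversed to -0.17 with the Control libraries split, where the shared controls no longer add to it. Fits on fewer libraries or only 2 groups have fewer residual degrees of freedom, and stricter thresholds pass fewer genes by construction; for the other alternatives the cause was not tested. Same-numbered libraries showed no steady pairing for the block (correlations of deviations from -0.54 to 0.54, mean 0.072 against -0.023 for other pairs, and 6 of 15 libraries correlating best with their own number). All correlations were above 0 for numbers 1 and 3 and mixed in sign for 2, 4 and 5. Whether the numbers pair the samples thus stays open. Of the named genes called in High against Control, 196 of 588 values under alternatives fell short of the threshold and 0 reversed, and of those in High against Low 329 of 966 fell short and 0 reversed. Of genes not called, 22 values passed in Low against Control and 5 in High against Low. Depth was 21.2 M counts or more in every library, and the self-test passed 53.5% of genes given a 2-fold change in High against Control. The genes of that self-test were drawn independently of each other, so this share may not hold for the real genes.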

Other observations

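The genes, globins and Hox transcripts below were chosen after their values were seen, and the splits of the libraries were planned before. Genes outside the naming rule or not yet described include several called between High and Control in all 10 fits that left out 1 library. HCCS (ENSDARG00000099358), a heme lyase of cytochrome c, rose from 19.2 ± 1.25 to 29.1 ± 2.03 CPM (SD, n = 5; log2 fold change 0.59, SE 0.075, edgeR quasi-likelihood adjusted p = 0.005). DHRS13 (ENSDARG00000026322), a dehydrogenase gene, rose from 21.3 ± 2.47 to 36.9 ± 5.85 CPM (edgeR adjusted p = 0.0097). REL (ENSDARG00000055276), a transcription factor of the NF-kB family, was at 26.9 ± 5.1 CPM in Control, 20.3 ± 3.24 in Low and 12.9 ± 2 in High (edgeR adjusted p = 0.0097, High against Control). The kinase gene NEK6 (ENSDARG00000037963) fell from 14.1 ± 2.21 to 7.3 ± 0.8 CPM and bnip4 (ENSDARG00000022832) from 13 ± 1.34 to 6.29 ± 1.44 CPM (edgeR adjusted p = 0.011 for both). TMEM175 (ENSDARG00000076376), too low in level for the rule, had 0.966 ± 0.321 CPM in Control, 0.819 ± 0.317 in Low and 0.0558 ± 0.0674 in High.

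Some lists not described in the report passed by camera alone. Between High and Control, proteasome genes had a median log2 fold change of 0.19 (adjusted p = 0.00085, and 0.86 with an estimated correlation), hemoglobin and heme genes 0.31 (adjusted p = 0.0019, and 0.72 with an estimated correlation) and lens crystallin genes -0.22 (adjusted p = 0.002, and 0.86 with an estimated correlation). Between High and Low, pigment cell genes had 0.23 (adjusted p = 0.00024, and 0.37 with an estimated correlation), and neuronal differentiation and synapse genes had -0.23 (adjusted p = 0.00024, and 0.56 with an estimated correlation). Lists of DNA methylation and chromatin modifiers and of mitochondrially encoded genes passed in no comparison.

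Globin transcripts differed widely between libraries of a group. The alpha globin gene hbaa1 had 3.75 CPM in High 4, 242 in High 5 and 285 in Low 5, and 660 to 2631 in the 12 other libraries. The embryonic globin gene hbae3 had 349 CPM in High 4, 376 in High 5 and 214 in Low 5, 0.182 to 10.8 in the other Low libraries, 0.451 in High 3, 117 and 164 in High 1 and 2, and 3.73 to 159 in Control. Only in High 4 and High 5 did hbae3 exceed hbaa1. Whether the balance of these globins bears on the stated age or on developmental pace was not tested. Posterior Hox genes stood out in Low 5, with HOXC10 at 4.57 CPM (0 to 0.592 elsewhere), HOXB13 at 3.71 (0 to 0.0818 elsewhere), and hoxa10b at 5.38 against 0.0729 to 0.435 in the other Low libraries. These other Low libraries also lay below every Control and High library in hoxa10b, at 0.8587 to 2.596 CPM in Control and 0.5558 to 2.779 in High. The same held for hoxa13b, at 0 to 0.3954 CPM against 0.6375 to 2.212 in Control and 0.4169 to 3.156 in High. For HOXD10 and HOXD11 the ranges overlapped, and all these levels are low. NCOR1 was high or low within a group, at 2.3 CPM in Low 1 and 3.82 in Low 5 against 19.7 to 49 in the other Low libraries, with 12.8 to 43 in Control and 1.48 to 3.15 in High.

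For the gene counts, 100 splits of the libraries into groups of the same sizes, the real one included, were compared. For High against Control 1 split, the real one with 115 genes, reached that count and the highest other had 5. For the slope on diet arsenic 1 split reached the real 63, and the highest other had 1. These shares were 0.035 after Benjamini-Hochberg adjustment over the 7 counts compared in this way. Such counts are thus unlikely from a random split, if the libraries are independent samples. The labels do not say that libraries came from separate clutches or parents, so the splits cannot tell diet from differences between those. For High against Low 3 splits reached the real 377 genes, a share under 0.05 that was 0.07 after Benjamini-Hochberg adjustment over the 7 counts, so chance is not firmly excluded. The highest other called 4139 genes, which points to a structure of the samples apart from their groups. For Low against Control, with 0 genes, all 100 splits reach the count by definition, so this share carries no information. It is still among the 7 counts of the adjustment, and the highest other split called 1477 genes. For lists, chance cannot be excluded in Low against Control, where 28 splits called the real 21 or more (highest other 27), or in High against Control, where 22 splits called the real 22 or more (highest other 32). In High against Low 4 splits called the real 29 or more (highest other 31), a share that was also 0.07 after that adjustment.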
